A study of Mus musculus with 15 samples.

How the data were processed

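Gene expression was measured with Affymetrix mouse arrays in spleen B cells and T cells from mice with a mixed strain background, per the labels' protocols. The 15 arrays fall into 5 groups of 3: B cells at 0 h, B cells after 4 h with 25 ug/ml lipopolysaccharide (LPS), T cells at 0 h, and T cells after 4 h or 14 h with 7.5 ug/ml concanavalin A (ConA). The labels state that 100 ng of total RNA per sample was labelled with a 3' IVT Express kit. They do not say whether the replicates came from separate animals or separate cultures.

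The deposited values are log2 signals made by the authors with GCRMA, a background correction and normalization between arrays, per the submitters' processing notes. The version of that tool is not given in the sources used here. The table holds 45101 probe sets, of which 64 are controls, and no probe set was centred. The lowest value, 2.24, is a floor shared by 39.2% of all values, and the highest is 15.9. A change against a group near this floor understates the true change and is a lower bound on it. Equal RNA mass was labelled and the arrays were normalized to each other, so a change in the amount of RNA per cell is not visible in these values.

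Probe sets were named from the platform's gene table, with symbols checked by Entrez number against a RefSeq gene table. That check found 34754 of the 34958 probe sets with 1 gene symbol, and it changed 0 symbols. Probe sets listed with several genes, 932 in all, and the 9211 listed with none were left out of the gene-level tests. For each of 18194 genes the probe set with the highest mean over all arrays was used. The 9045 genes whose highest group mean was at least 5 on the log2 scale were tested. Array medians over all probe sets lay between 2.42 and 2.57. Correlations between arrays of a group lay between 0.995 and 0.999, and those between groups between 0.893 and 0.990. For arrays, the number of replicates sets the precision.

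One group-means model over the 15 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with its default single prior). The fit had 10 residual degrees of freedom, to which the prior added 3.16. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, and a gene was called changed at an adjusted p under 0.05. Errors given with log2 changes are standard errors from this fit, and errors given with levels are standard deviations over 3 arrays. The comparisons were LPS 4 h against 0 h in B cells, ConA 4 h and 14 h each against 0 h in T cells, ConA 14 h against 4 h, B against T cells at 0 h, and the interaction between cell type and the 4 h response.

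The 24 gene lists and 9 cell marker lists were fixed before the data were examined, as were the comparisons, the filters, the tests, the rule for named genes and most alternatives. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The test was repeated with an estimated correlation, and with fry, which asks whether a list's members move one way on balance and compares them with no other genes. Counts of members that rose or fell use p-values adjusted over all genes tested. For the counts printed here, those adjusted over the list alone were the same except where they are given. Marker lists were counted and not tested as sets. A further 6 lists were added after the data had been seen: Y-linked genes, their X-linked homologues, red pulp macrophage genes, LPS-induced macrophage genes, erythroid progenitor genes and late erythroid genes.

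The rule for named genes took Myc, then the 8 largest rises and 8 largest falls (5 and 5 in the last 3 comparisons) among changed genes with a mean of at least 7 in the higher group and no overlap between the arrays. It left out antigen receptor segments and predicted genes without a name. From each list it took up to 4 changed members with the largest change, or the brightest members where fewer than 2 had changed. Members that moved against most of their list, or that did not pass, were named after their values were seen.

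The number of genes at or above level 5 per array was compared with a two-sided exact permutation test, whose smallest possible p with 3 against 3 arrays is 0.1. The share of changed genes that rose was described in 5 equal bins of the mean level, without a test. Responses were correlated across genes, and genes are not independent replicates. For the T cell responses that share the 0 h arrays, 100 simulated data sets without any effect gave the correlation that the sharing alone produces.

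The pipeline was tested on simulated data. With 50 genes changed per size, it recovered 96% of the 2-fold and 72% of the 1.5-fold changes for LPS in B cells, with 12 false calls among 8820 unchanged genes. For the interaction it recovered 76% of the 2-fold and 38% of the 1.5-fold changes. A simulated shift of 1 list was found in each comparison, with 0 of 23 other lists called. Genes were simulated as independent, so that count does not cover false calls of lists whose genes are correlated.

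The alternatives were other level filters, other ways to combine probe sets, 3 further normalizations, a fold threshold and limma's treat at 1.5-fold, the trend and robust options of eBayes, fits of only the arrays compared, and leaving out each array in turn. A block for the replicate number was also fitted. Chosen after the data were seen were a fit without 2 T cell arrays with a weak 5' spike-in signal, that signal as a covariate, and a fit without genes whose mean lay under 4 in any group. Planned pseudocounts were not run, since the deposited values were already on a log scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.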

Results

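The series profiled resting and activated mouse lymphocytes, and its title raises the question of whether the transcription factor Myc acts on expressed genes in general. B cells were activated with LPS, a bacterial ligand of Toll-like receptor 4, and T cells with ConA, a plant lectin that cross-links surface glycoproteins. Of the 18194 genes on the arrays, 8108 ± 42.9 (SD, n = 3) reached a log2 signal of 5 in B cells at 0 h and 7701 ± 43.2 after LPS. In T cells the number was 8338 ± 40.6 at 0 h, 8216.67 ± 37.1 at 4 h and 8245 ± 27.8 at 14 h. The 3 arrays per group limit the precision of every value. No group was cultured without LPS or ConA, so a change from 0 h may come from these or from culture itself.

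Spike-in and ribosomal RNA control signals differed between arrays and between groups. The dap spike-in RNA gave a 3' signal that exceeded its 5' signal by 4.52 on T 0 h replicate 2 and by 5.35 on T ConA 4 h replicate 1 (log2), against 1.39 to 1.96 on the other T arrays. In B cells this difference averaged 0.75 ± 0.05 at 0 h and 0.39 ± 0.17 after LPS (SD, n = 3). Control probe sets for the 3' part of 18S ribosomal RNA read 5.78 ± 0.33 in B cells and 10.02 ± 0.72 in T cells at 0 h. All B arrays differed from all T arrays in these spike-in and 18S controls. A part played by labelling in the differences between B and T cells was thus not excluded. With the spike-in difference as a covariate 6734 genes differed between B and T cells at 0 h. That count does not decide on labelling. The spike-in difference was at most 0.78 on B arrays and at least 1.39 on T arrays, so the covariate cannot be separated from cell type. The 3' minus 5' difference of actin, an RNA of the cells themselves, averaged 0.49 ± 0.02 in B cells and 0.45 ± 0.05 in T cells at 0 h (SD, n = 3). It was highest on T ConA 4 h replicate 1, at 0.91.

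B cells after 4 h of LPS raised Myc 29.2-fold, from 7.14 ± 0.20 to 12.01 ± 0.18 (log2, SD, n = 3; change 4.87 ± 0.43 SE, adjusted p = 1.08e-07). The largest rises were in the chemokine Cxcl10 (8.62 ± 0.16), the cytokine Il6 (8.36 ± 0.07), Grasp (7.97 ± 0.20), the interleukin 2 receptor chain Il2ra (7.79 ± 0.13) and the chemokine Ccl3 (7.67 ± 0.08). They were followed by the nuclear receptor Nr4a3 (7.50 ± 0.16), Mir155hg, the host transcript of a microRNA (7.40 ± 0.18), and the interferon-induced Ifit1 (7.36 ± 0.22). Besides Xist, which is described with the sex-linked genes, the largest falls were in Marchf1, a ubiquitin ligase acting on MHC class II (-9.38 ± 0.06), the egress receptor S1pr1 (-8.20 ± 0.14) and Cmah (-8.12 ± 0.16). Trim7 (-8.01 ± 0.12), Tm6sf1 (-7.97 ± 0.15), the kinase gene Lrrk2 (-7.88 ± 0.14) and the homeobox gene Hhex (-7.74 ± 0.22) came next. Of 9045 genes tested, 3400 rose and 3824 fell, and 1689 and 2181 of these did so at least 2-fold.

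Growth and biosynthesis lists rose in B cells. All 39 tested genes of ribosome biogenesis rose, with a median of 2.38 (camera adjusted p = 3.25e-15), led by Rrp9 (4.87 ± 0.28), Rrp12 (4.59 ± 0.10) and the RNA polymerase I subunit Polr1b (3.72 ± 0.13). All 21 genes of nucleotide, one-carbon and polyamine synthesis rose (median 2.02, adjusted p = 3.29e-08), among them Mthfd2 (4.10 ± 0.14), the spermidine synthase Srm (3.87 ± 0.08) and the CTP synthase Ctps (3.16 ± 0.08). Of 18 aminoacyl-tRNA synthetases 16 rose (median 2.23, adjusted p = 1.06e-06), with Cars at 3.89 ± 0.17. Qars (-0.19) and Vars (-0.13) did not pass. Of 18 translation factors 16 rose (median 1.70, adjusted p = 5.56e-06), with Eif2b3 at 3.21 ± 0.11, while Eef2 fell (-0.54 ± 0.07). Cholesterol synthesis rose in 15 of 17 genes (adjusted p = 5.25e-06), among them the squalene epoxidase Sqle (4.94 ± 0.07) and Idi1 (4.27 ± 0.08). Ebp (-1.06 ± 0.07) and Dhcr7 (-0.76 ± 0.30) fell. All 19 chaperones (median 1.30, adjusted p = 1.98e-07; Hsph1 2.53 ± 0.07) and 26 of 28 proteasome genes (median 0.97, adjusted p = 2.55e-07; Psme3 2.11 ± 0.07) rose. Of 23 genes of Pol II transcription 16 rose and 2 fell, Polr2g (-0.51 ± 0.09) and Ccnt2 (-0.53 ± 0.07) (median 0.68, adjusted p = 0.00166, and adjusted p = 0.0660 with an estimated correlation).

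Inflammatory and signalling lists rose as well. Interferon-stimulated genes rose in 19 of 20 (median 3.09, adjusted p = 1.07e-07), with Oasl1 at 7.33 ± 0.32 and Usp18 at 5.09 ± 0.13, while Stat2 (0.74) did not pass. NF-kappaB targets rose in 17 of 19 (median 2.35, adjusted p = 6.61e-07), with the survival gene Bcl2l1 at 4.32 ± 0.10 and Traf1 at 4.19 ± 0.10, and Irf1 fell (-0.38 ± 0.10). Feedback genes of cytokine signalling rose in 14 of 15 (median 2.24, adjusted p = 1.60e-05), with Batf at 4.46 ± 0.09 and Socs3 at 3.60 ± 0.09. Activation surface molecules rose in 14 of 19 (median 1.76, adjusted p = 5.25e-05), with the costimulatory ligands Cd80 (4.30 ± 0.21) and Cd86 (3.87 ± 0.18), while Tnfrsf18 fell (-0.49 ± 0.11). Immediate early genes rose in 15 of 20 (median 1.52, adjusted p = 0.000946), with Jun at 7.02 ± 0.23 and Atf3 at 5.34 ± 0.14. Egr3 (-2.34 ± 0.09), Zfp36 (-1.56 ± 0.08), Btg2 (-1.21 ± 0.08) and Klf6 (-0.33 ± 0.08) fell. Cytokines and chemokines rose in 11 of 19 (median 1.00, adjusted p = 0.000946), with Il1b at 6.73 ± 0.15, and Lta fell (-1.32 ± 0.10). That call was lost with adjusted p = 0.0816 with an estimated correlation.

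Other lists fell or went both ways in B cells. Quiescence genes fell in 15 of 23 (median -1.36, adjusted p = 0.0119, and adjusted p = 0.0792 with an estimated correlation), with Rbl2 at -4.01 ± 0.17 and Ccng2 at -3.90 ± 0.14. Ccr7 (3.44 ± 0.13), Il7r (3.02 ± 0.17), Slfn2 (1.62 ± 0.10), Satb1 (0.77 ± 0.06) and Lef1 (0.61 ± 0.24) of that list rose. All 18 G2/M genes fell (median -0.92, adjusted p = 0.00157, and adjusted p = 0.0660 with an estimated correlation), among them Aurkb (-2.02 ± 0.23) and Ccnb2 (-1.20 ± 0.10). Erythroid progenitor genes fell as well, in 12 of 12 (median -1.45), and which cells the G2/M falls came from was not tested. All 11 genes of MHC class II presentation fell (median -0.78, adjusted p = 0.000774, and adjusted p = 0.158 with an estimated correlation), with H2-Oa at -5.13 ± 0.10 and the transactivator Ciita at -4.40 ± 0.39. ER chaperones rose in 14 of 20 and 4 fell, or 5 adjusted over the list alone (median 0.49, adjusted p = 0.0392, and adjusted p = 0.0660 with an estimated correlation). Those that fell were Pdia4 (-3.90 ± 0.11), Edem1 (-1.04 ± 0.08), Xbp1 (-0.49 ± 0.07) and Calr (-0.28 ± 0.09). The lists not called were G1/S (11 rose and 16 fell of 32, with cyclin Ccnd2 up 4.57 ± 0.08 and Tk1 at -2.81 ± 0.21) and glycolysis (10 rose and 4 fell of 16; Hk2 4.59 ± 0.21; adjusted p = 0.0537). Neither were oxidative phosphorylation (12 rose and 3 fell of 27, or 10 and 3 adjusted over the list alone), the Bcl2 family (5 rose and 2 fell of 14), the Myc network (6 rose and 2 fell of 11, with Mxd4 at -6.06 ± 0.17) and cytoplasmic ribosomal proteins (4 rose and 10 fell of 29, or 4 and 9 adjusted over the list alone).

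Markers of other cell types moved with LPS in the B cell arrays. Of 8 monocyte, macrophage and neutrophil markers 7 fell (median -3.54), among them the growth factor receptor Csf1r (-6.97 ± 0.13) and lysozyme Lyz2 (-4.40 ± 0.19), while Mpeg1 read 11.15 at 0 h and 11.48 after LPS. Plasma cell markers fell in 2 of 2. Of these, Mzb1 (-4.12 ± 0.09) read 12.90 in B cells at 0 h, so its fall does not by itself show fewer plasma cells. Erythroid markers fell in 4 of 4 (median -1.55, with Car1 at -2.86 ± 0.11), and stromal and endothelial markers in the 2 tested, Pecam1 (-2.30 ± 0.22) and Vcam1 (-6.32 ± 0.14). The other 7 of that list lay at the floor at 0 h, and Vcam1 is counted among the red pulp macrophage genes too. The platelet marker Ppbp fell (-3.40 ± 0.10), and Pf4 (-0.40) did not pass. Dendritic cell markers rose in 2 of 4, Zbtb46 (4.62 ± 0.13) and Flt3 (2.29 ± 0.26), and Itgax fell (-3.74 ± 0.06). Among 4 NK cell markers Klrd1 (-3.69 ± 0.18) and Prf1 (-2.04 ± 0.17) fell and Eomes rose (1.04 ± 0.23). B cell markers fell in 10 of 12 (median -1.44), with Cd22 at -4.96 ± 0.15 and Cd79a at -2.57 ± 0.07, and T cell markers fell in 5 of 12. Of the latter, Cd2 (-5.21 ± 0.10) read 10.93 in B cells at 0 h, while Cd3d (2.82), Cd3g (2.40) and Thy1 (2.25) lay near the floor. The fall of Cd2 thus does not show fewer T cells. For 489 of the falls the mean after LPS lay under 4, and for 230 of the rises the mean at 0 h did, so those changes are lower bounds.

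**Figure D1:**
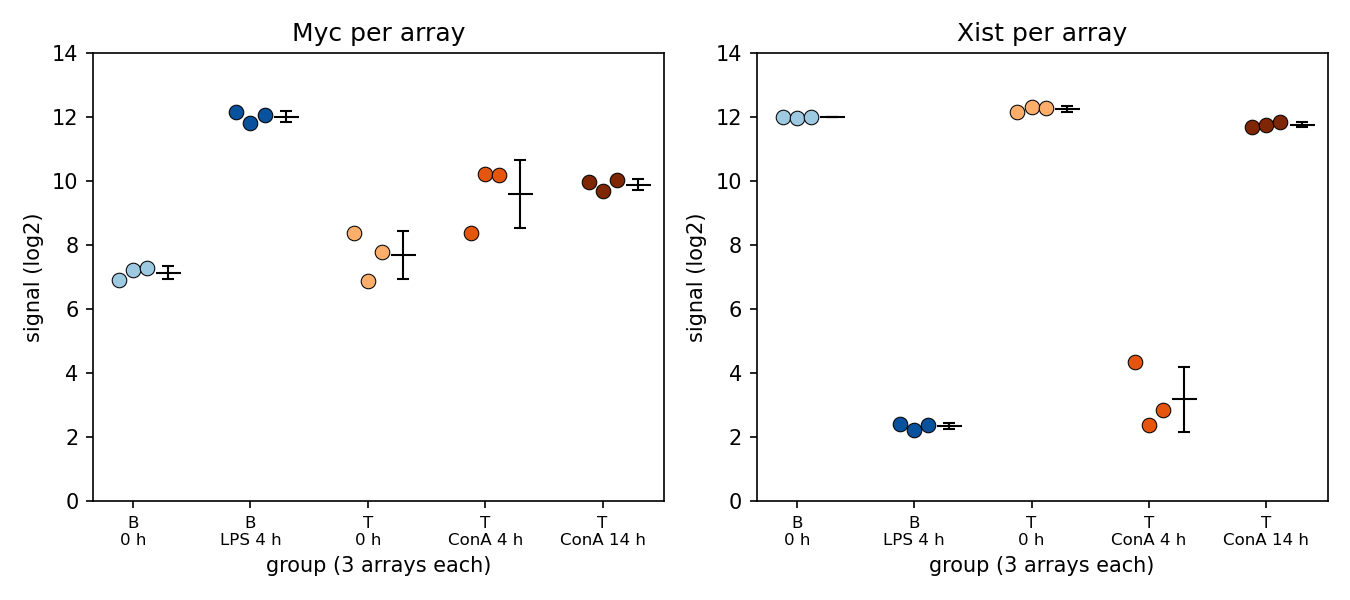
Signal of Myc (left) and Xist (right) on each of the 15 arrays, on a log2 axis, with the mean and SD of the 3 arrays beside each group. Myc rose from a mean of 7.14 to 12.01 in B cells and from 7.68 to 9.59 and 9.89 in T cells, while Xist lay near the floor at 4 h in both cell types.

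T cells after 4 h of ConA raised Myc 3.75-fold, from 7.68 ± 0.75 to 9.59 ± 1.06 (SD, n = 3; change 1.91 ± 0.43 SE, adjusted p = 0.00143), and 2.52 without T ConA 4 h replicate 1. The arrays with the weak 5' spike-in signal gave the lowest Myc value of their groups, 6.88 and 8.37. The largest rises were in the transcription factor Irf4 (8.31 ± 0.19), Il6 (7.96 ± 0.07), the chemokine Ccl4 (6.31 ± 0.31), the transcription factor Crem (6.26 ± 0.13) and Lad1 (6.22 ± 0.12). Mir155hg (6.02 ± 0.18), Sema7a (5.97 ± 0.10) and the signalling inhibitor Spry1 (5.90 ± 0.15) followed. Besides Xist, the largest falls were in Dtx1, a regulator of Notch signalling (-7.49 ± 0.07), Scg5 (-5.65 ± 0.15), Pdlim4 (-5.52 ± 0.14) and Tet1, an enzyme of DNA demethylation (-5.44 ± 0.11). Lypd6b (-5.35 ± 0.15), Slc16a5 (-5.26 ± 0.06) and Ampd1 (-5.13 ± 0.10) came next. In all, 3024 genes rose and 2938 fell, 845 and 1044 of them at least 2-fold, and without the 2 arrays just named 5707 genes changed. Which direction held the majority depended on the normalization, with 2967 rises and 3028 falls after array medians were set equal and 2900 and 3159 after cyclic loess.

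Cytokine and signalling lists rose at 4 h. Cytokines and chemokines rose in 16 of 19 genes, or 17 adjusted over the list alone (median 3.001, adjusted p = 8.75e-09), with Il2 at 5.27 ± 0.13 and Xcl1 at 4.85 ± 0.17, while Ccl5 fell (-1.86 ± 0.12). Activation surface molecules rose in 18 of 19 (median 2.01), with Il2ra at 3.99 ± 0.13 and Tnfrsf9 at 3.85 ± 0.09. Feedback genes of cytokine signalling rose in 12 of 15 (median 1.74, adjusted p = 1.64e-06; Irf8 4.07 ± 0.10, Socs1 3.62 ± 0.12). NF-kappaB targets rose in 16 of 19 (median 0.99, adjusted p = 2.33e-06; Cd83 3.84 ± 0.10), and Tnip1 fell (-0.51 ± 0.07). Immediate early genes rose in 11 of 20 (median 0.65, adjusted p = 0.000448), with Nr4a2 at 5.54 ± 0.15 and Fosl2 at 5.15 ± 0.09, and Fos (-0.32 ± 0.11), Btg2 (-0.39 ± 0.08) and Klf6 (-0.37 ± 0.08) fell. The Bcl2 family rose in 8 of 14 and fell in 3, with the death gene Pmaip1 at 1.80 ± 0.10 and the survival gene Bcl2l1 at 1.62 ± 0.10 (median 0.42, adjusted p = 0.0462, and adjusted p = 0.0712 with an estimated correlation).

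Biosynthesis lists rose and cell cycle lists fell at 4 h. Ribosome biogenesis rose in 38 of 39 genes (median 1.255, adjusted p = 2.30e-14), with Polr1b at 2.45 ± 0.13 and Nop16 at 1.88 ± 0.09, and Ubtf fell (-0.26 ± 0.06). Nucleotide synthesis rose in 18 of 21 (median 1.04, adjusted p = 1.80e-06; the ornithine decarboxylase Odc1 2.12 ± 0.09), and tRNA synthetases in 16 of 18 (median 0.82, adjusted p = 6.49e-05; Rars 1.37 ± 0.14), while Qars (-0.34 ± 0.10) and Sars (-0.24 ± 0.07) fell. Translation factors rose in 14 of 18 (median 0.71, adjusted p = 0.000159; Eif1a 1.72 ± 0.11), and Eif4ebp1 fell (-0.44 ± 0.14). Cholesterol synthesis rose in 12 of 17 (median 0.98, adjusted p = 0.00118; Cyp51 2.39 ± 0.10), and Dhcr7 (-1.19 ± 0.30) and Mvd (-0.99 ± 0.16) fell. Chaperones rose in 18 of 19 (median 0.57, adjusted p = 6.74e-06; Hspa9 1.37 ± 0.13) and the proteasome in 25 of 28 (median 0.65, adjusted p = 4.29e-07; Psmd1 1.13 ± 0.07). Pol II genes rose in 13 of 23 and fell in 2, Polr2g (-0.63 ± 0.09) and Supt5 (-0.25 ± 0.06) (adjusted p = 0.0120, and adjusted p = 0.0987 with an estimated correlation). G2/M genes fell in 16 of 18 (median -0.97, adjusted p = 1.84e-05; Cdk1 -1.94 ± 0.12, Mki67 -1.65 ± 0.10). Erythroid progenitor genes fell in the same arrays (median -2.39). Whether the falls of cell cycle genes took place in the T cells or in other cells of the preparation was not tested. G1/S genes fell in 17 of 32 and rose in 5, Mcm6 (0.62 ± 0.07) the most (median -0.45, adjusted p = 0.0125, and adjusted p = 0.0637 with an estimated correlation). Quiescence genes fell in 15 of 23 (median -0.84, adjusted p = 0.00788, and adjusted p = 0.0637 with an estimated correlation), with Pik3ip1 at -2.64 ± 0.16 and Txnip at -2.30 ± 0.09. Interferon-stimulated genes fell in 12 of 20 (median -0.49, adjusted p = 0.0462, and adjusted p = 0.0987 with an estimated correlation), and Gbp2 (3.26 ± 0.08), Zbp1 (1.20 ± 0.08) and Parp14 (0.80 ± 0.08) rose. Ribosomal proteins fell in 12 of 29, or 10 adjusted over the list alone, by a median of -0.13 (adjusted p = 0.0462, and adjusted p = 0.350 with an estimated correlation). Not called were glycolysis (9 rose, 4 fell), ER chaperones (13 rose, 4 fell), MHC class II (6 rose, 4 fell), the Myc network (3 rose, 3 fell) and oxidative phosphorylation (8 rose, 3 fell, or 7 and 3 adjusted over the list alone). The medians of the last pair of lists changed sign under cyclic loess normalization.

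Cell markers and sex-linked genes moved in the T cell arrays too. T cell markers fell in 7 of 12 and rose in 2 (median -0.62; Thy1 -2.97 ± 0.12, Cd4 -2.16 ± 0.13), and NK cell markers that CD8 T cells also express fell in 3 of 4 (Nkg7 -2.19 ± 0.16). B cell markers rose in 6 of 12 (Cr2 3.23 ± 0.18), and the neutrophil genes S100a8 (2.71 ± 0.19) and S100a9 (2.45 ± 0.20) rose while Lyz2 (-0.98 ± 0.19) and Lyz1 (-0.80 ± 0.12) fell. Erythroid progenitor genes, a list added after the data were seen, fell in 11 of 12 (median -2.39), among them the water channel Aqp1 (-4.79 ± 0.07) and the erythroid factor Klf1 (-4.77 ± 0.10). Xist, the RNA that coats the inactive X chromosome, averaged 11.997 in B cells and 12.25 in T cells at 0 h, 2.35 and 3.19 at 4 h, and 11.77 in T cells at 14 h. The Y-linked genes Eif2s3y, Kdm5d and Uty were present in every group, and all 3 rose in T cells at 4 h (median 0.53) and fell at 14 h against 0 h (median -0.79). In B cells none of the 3 changed (Eif2s3y 0.17 ± 0.13) on the brightest probe set of each gene. A dimmer probe set of Eif2s3y went from 5.21 to 2.45. Dimmer probe sets of Uty went both ways, from 4.40 to 5.23 and from 5.23 to 4.88, and a dimmer Kdm5d probe set went from 4.94 to 5.21. Those Y-linked genes were also chosen after the data were seen.

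**Figure D2:**
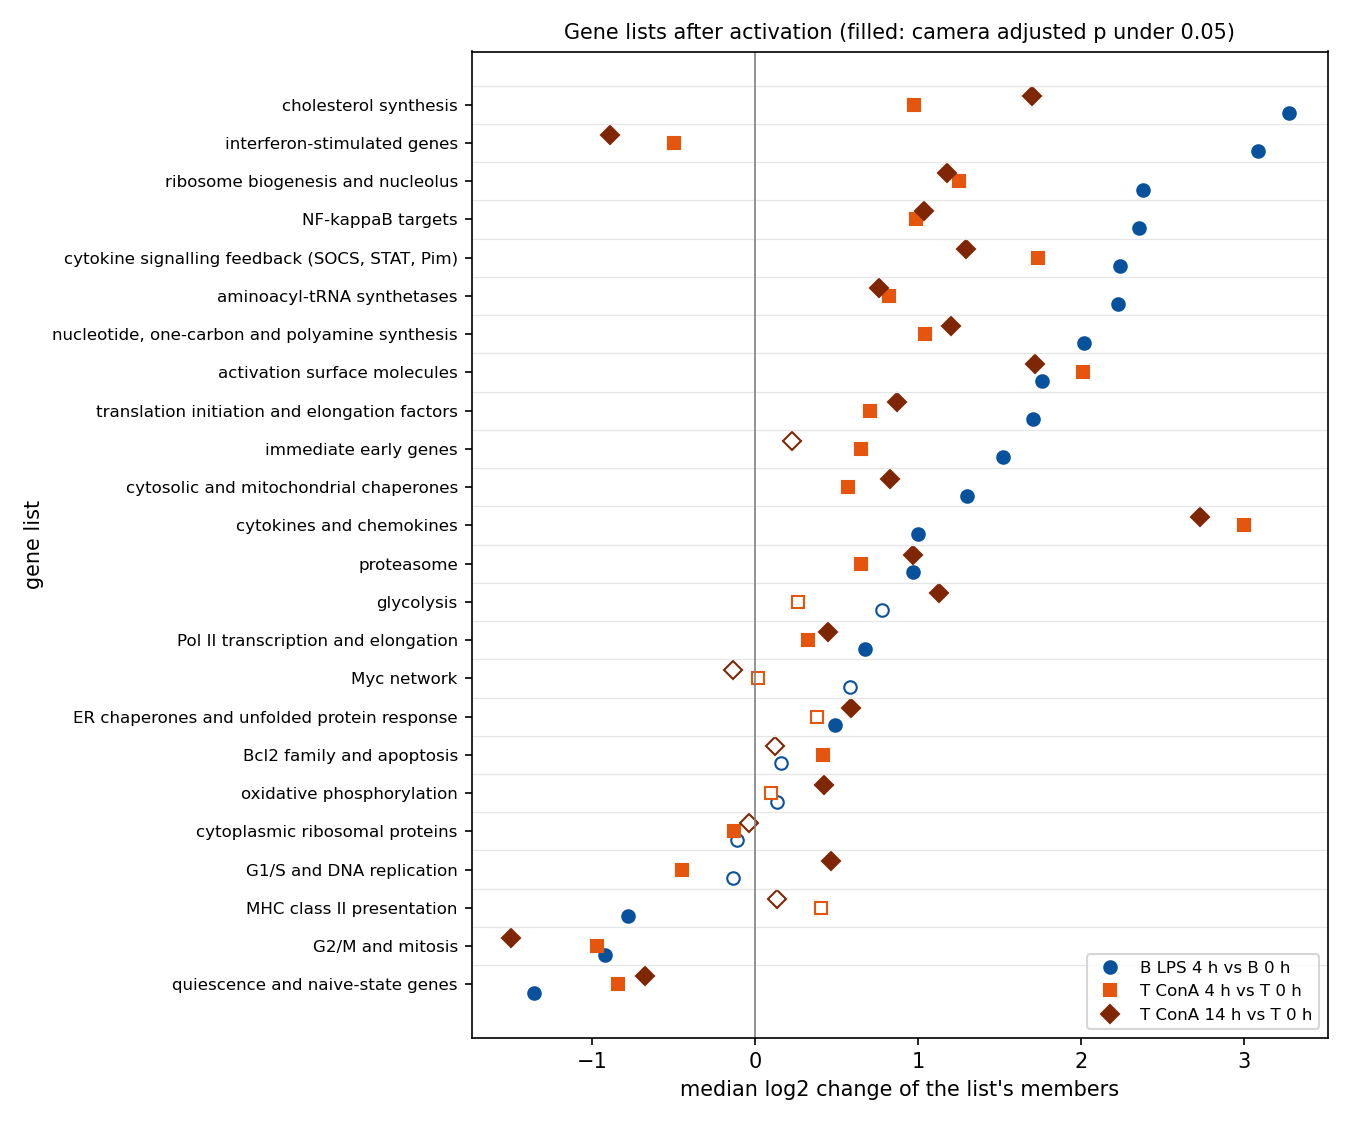
Median log2 change of the tested members of each of the 24 gene lists in the 3 activation comparisons, with filled symbols where camera's adjusted p at the preset correlation was under 0.05. Ribosome biogenesis had medians of 2.38, 1.255 and 1.18, and interferon-stimulated genes had medians of 3.09, -0.49 and -0.89.

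T cells after 14 h of ConA held Myc 4.62-fold above 0 h, at 9.89 ± 0.18 (SD, n = 3; change 2.21 ± 0.43 SE, adjusted p = 0.000423). The change was 1.81 without the 2 T arrays with the weak 5' spike-in signal and 1.60 with that signal as a covariate. The largest rises were in Irf4 (7.85 ± 0.19), the inhibitory receptor Lag3 (6.72 ± 0.09), Tg (6.67 ± 0.11), the growth factor Il2 (6.15 ± 0.13) and Lad1 (6.04 ± 0.12), followed by Mir155hg (5.85 ± 0.18), Ccl4 (5.56 ± 0.31) and Spry1 (5.54 ± 0.15). The largest falls were in the heat shock genes Hspa1b (-6.59 ± 0.12) and Hspa1a (-5.88 ± 0.08), near-identical copies that probe sets may not separate, and in Lypd6b (-5.78 ± 0.15) and Dtx1 (-5.77 ± 0.07). Tmem163 (-5.70 ± 0.15), Ermap (-5.61 ± 0.20), Scg5 (-5.56 ± 0.15) and Klf1 (-5.54 ± 0.10) came next. Ermap and Klf1 belong to the erythroid progenitor genes, of which 11 of 12 fell (median -3.60). In all, 3309 genes rose and 2882 fell, 954 and 992 of them at least 2-fold. The majority turned to falls with array medians set equal (3056 rises and 3156 falls) and after cyclic loess (2884 and 3345).

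Biosynthesis lists also stood above 0 h at 14 h. All 39 ribosome biogenesis genes (median 1.18, adjusted p = 4.20e-13; Noc4l 1.83 ± 0.11), all 18 tRNA synthetases (median 0.76, adjusted p = 5.42e-06; Wars 2.11 ± 0.12) and all 28 proteasome genes (median 0.97, adjusted p = 1.18e-09; Psmd7 1.62 ± 0.24) rose. Nucleotide synthesis rose in 19 of 21 (median 1.20; Umps 1.99 ± 0.21), translation factors in 15 of 18 (median 0.87; Eif4e 1.22 ± 0.19), chaperones in 18 of 19 (median 0.83; Hspd1 1.502 ± 0.08) and cholesterol synthesis in 16 of 17 (median 1.70; Fdps 2.54 ± 0.12). Glycolysis rose in 12 of 16 (median 1.13, adjusted p = 0.00162), with Hk2 at 3.88 ± 0.21 and Tpi1 at 2.14 ± 0.08, while the glucose transporter Slc2a3 (-1.58 ± 0.09, seen only on probe sets that may match other transcripts) and Hk1 (-0.40 ± 0.14) fell. Oxidative phosphorylation rose in 24 of 27 (median 0.43, adjusted p = 3.13e-05, and adjusted p = 0.0638 with an estimated correlation; Cycs 1.07 ± 0.08). Pol II genes rose in 18 of 23 (adjusted p = 0.00321, and adjusted p = 0.0638 with an estimated correlation), and ER chaperones in 12 of 20 with 4 falling (adjusted p = 0.0344, and adjusted p = 0.0604 with an estimated correlation; Sdf2l1 1.68 ± 0.10). G1/S genes rose in 21 of 32 and fell in 6, with Gins1 at 1.496 ± 0.15 and E2f2 at -2.98 ± 0.20 (median 0.47, adjusted p = 0.0175, and adjusted p = 0.0638 with an estimated correlation).

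Signalling lists kept their direction in the same comparison. Cytokines and chemokines rose in 16 of 19 (median 2.73, adjusted p = 6.63e-07; Ccl22 5.38 ± 0.12, Lif 5.18 ± 0.14), while Ccl5 (-3.51 ± 0.12) and Il1b (-0.42 ± 0.15) fell. Surface molecules rose in 16 of 19 (median 1.72; Il2ra 4.60 ± 0.13), NF-kappaB targets in 16 of 19 (median 1.04; Rel 3.35 ± 0.16), and feedback genes in 13 of 15 (median 1.30; Pim2 2.83 ± 0.12). G2/M genes fell in 17 of 18 (median -1.49, adjusted p = 2.18e-06; Mki67 -3.10 ± 0.10, Ube2c -2.75 ± 0.18), and Aurka rose (0.60 ± 0.22). With erythroid progenitor genes falling too (median -3.60), the G2/M falls need not have taken place in the T cells, which was not tested. Quiescence genes fell in 17 of 23 (median -0.67, adjusted p = 0.00274; Il7r -3.26 ± 0.17). Interferon-stimulated genes fell in 12 of 20, or 13 adjusted over the list alone, and 5 rose (median -0.89, adjusted p = 0.0237, and adjusted p = 0.0652 with an estimated correlation), with Isg20 at -2.21 ± 0.15 and Zbp1 at 2.33 ± 0.08. Not called were immediate early genes (10 rose and 6 fell), the Myc network (4 rose and 5 fell), ribosomal proteins (2 rose and 6 fell), MHC class II (4 rose and 4 fell) and the Bcl2 family (6 rose and 2 fell). Among markers, monocyte genes fell in 6 of 8 (median -1.42; S100a9 -3.55 ± 0.20) and T cell markers in 7 of 12 (median -0.51; Thy1 -2.24 ± 0.12). B cell markers rose in 2 of 12 and fell in 4, or in 2 adjusted over the list alone.

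Between 4 h and 14 h of ConA, T cells raised genes of DNA replication, energy metabolism and sterol synthesis. G1/S genes rose in 27 of 32, or 28 adjusted over the list alone (median 0.74, adjusted p = 2.09e-11), with Uhrf1 at 2.34 ± 0.16 and the licensing factor Cdc6 at 2.29 ± 0.14. Cholesterol synthesis rose in 15 of 17 (median 0.90, adjusted p = 1.12e-06; Mvd 1.94 ± 0.16), glycolysis in 13 of 16 (median 0.62, adjusted p = 4.85e-05; Tpi1 2.51 ± 0.08), and the proteasome in 21 of 28, or 22 adjusted over the list alone (median 0.33, adjusted p = 3.29e-05; Psma1 0.62 ± 0.07). Oxidative phosphorylation rose in 22 of 27, or 25 adjusted over the list alone (median 0.36, adjusted p = 1.59e-05, and adjusted p = 0.110 with an estimated correlation; Sdhd 0.85 ± 0.06). Immediate early genes fell in 16 of 20 (median -0.63, adjusted p = 6.95e-07), with Nr4a2 at -2.12 ± 0.15 and Egr2 at -1.84 ± 0.14, and Klf6 rose (0.52 ± 0.08). Feedback genes fell in 10 of 15, or 11 adjusted over the list alone (median -0.49, adjusted p = 0.0248, and adjusted p = 0.0782 with an estimated correlation; Bcl6 -2.07 ± 0.10), and G2/M genes in 8 of 18 (median -0.28, adjusted p = 0.0184, and adjusted p = 0.210 with an estimated correlation). Erythroid progenitor genes fell in 6 of 12 (median -0.47), and which cells the G2/M falls came from was not tested.

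The largest single rises in that comparison were Xist (8.58 ± 0.33), Lag3 (5.39 ± 0.09), Tg (4.63 ± 0.11), the chemokine Ccl22 (4.44 ± 0.12) and the adhesion molecule Selp (3.18 ± 0.21). The largest falls were the neutrophil genes S100a9 (-6.005 ± 0.20) and S100a8 (-5.52 ± 0.19), with Mpzl2 (-4.14 ± 0.15), St6galnac3 (-4.09 ± 0.29) and Prag1 (-3.82 ± 0.10). The value of Myc, 0.30 ± 0.43, did not pass (adjusted p = 0.601). Among cytokines Il1b (-3.39 ± 0.15) and Il6 (-3.07 ± 0.07) fell, and the list (7 rose and 9 fell, or 7 and 11 adjusted over the list alone) was not called. Changed genes numbered 4427, of which 2479 rose and 1948 fell. This balance also rests on the normalization, as array medians set equal gave 2238 rises and 2253 falls and cyclic loess gave 2162 and 2404.

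At rest, B cells and T cells differed in their lineage genes and in several functional lists. All 12 B cell markers were higher in B cells (median 8.69), among them the complement receptor Cr2 (10.63 ± 0.18), the antigen receptor component Cd79a (10.31 ± 0.07) and the adaptor Blnk (9.76 ± 0.06). All 12 T cell markers were lower (median -8.29), with the T cell receptor components Cd3d (-10.96 ± 0.15) and Cd3g (-10.95 ± 0.09) and the coreceptor Cd8b1 (-10.84 ± 0.12). The desaturase Scd1 (9.93 ± 0.09) and Siglecg (9.40 ± 0.10) were also among the genes most raised in B cells, and Bcl11b (-9.93 ± 0.13) and Igfbp4 (-9.71 ± 0.35) among those most raised in T cells. All 11 MHC class II genes were higher in B cells (median 5.28, adjusted p = 1.10e-10, and adjusted p = 0.101 with an estimated correlation; Cd74 6.63 ± 0.16). G2/M genes were higher in 17 of 18 (median 1.43, adjusted p = 7.19e-08; Mki67 2.49 ± 0.10), and G1/S genes in 15 of 32 with 9 lower (adjusted p = 0.0400, and adjusted p = 0.171 with an estimated correlation; Rrm2 2.42 ± 0.08). Erythroid progenitor genes were also higher in 9 of 12 and lower in 2 (median 2.04). Which cells of the preparations gave the G2/M difference was not tested. NF-kappaB targets were higher in 11 of 19 and lower in 6 (adjusted p = 0.0140, and adjusted p = 0.103 with an estimated correlation; Cd40 7.11 ± 0.19). Immediate early genes were lower in B cells in 14 of 20 (median -1.46, adjusted p = 0.0140, and adjusted p = 0.103 with an estimated correlation; Fos -7.50 ± 0.11), as was cholesterol synthesis in 14 of 17 (median -1.25, adjusted p = 0.0140, and adjusted p = 0.164 with an estimated correlation; Lss -2.57 ± 0.20). Markers of other cell types also differed: red pulp macrophage genes were higher in B cells in 11 of 11 (median 5.89), late erythroid genes in 7 of 7 (median 5.92; the anion exchanger Slc4a1 8.98 ± 0.15), and NK cell markers were lower in the 4 tested (median -6.07). Those 4, Nkg7, Klrd1, Eomes and Prf1, are also expressed by CD8 T cells, while Ncr1 (2.49), Klre1 (2.55), Klrk1 (3.02) and Gzma (3.51) of the same list were near the floor in T cells at 0 h. Myc at -0.54 ± 0.43 did not pass (adjusted p = 0.262), but it passed at -0.94 without the 2 T arrays with the weak 5' spike-in signal (adjusted p = 0.000534) and at -1.504 with that signal as a covariate (adjusted p = 1.39e-05). The covariate value is an extrapolation, since B and T arrays did not overlap in the spike-in difference.

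In the same comparison 2302 genes were higher in B cells and 4626 lower, and the median of all genes was -0.27. Setting the array medians equal moved that median by 0.25 and gave 3279 higher and 3501 lower, so the split between directions rests on the normalization. Of the lists it flipped in sign of the median, such as glycolysis and the proteasome, none had been called. The probe set used here disagreed with another probe set of the same gene for Mxi1, Rps9, Pfkp, Hk1, Kdm5d and Kdm5c.

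The 4 h responses of B and T cells were compared as an interaction, which asks for which genes the response differed between LPS in B cells and ConA in T cells. The rise of Myc was larger in B cells by 2.96 ± 0.61 (7.80-fold, adjusted p = 0.000690), and by 2.35 without T ConA 4 h replicate 1 (adjusted p = 0.000293). Interferon-stimulated genes responded more strongly in B cells in 18 of 20 (median 3.79, adjusted p = 2.48e-09; Ifit1 9.55 ± 0.31, Oasl1 7.43 ± 0.46, Mx1 5.59 ± 0.20), with Gbp2 the other way (-3.06 ± 0.11). The differences were positive for ribosome biogenesis in 38 of 39 (median 1.06, adjusted p = 1.46e-11; Rrp12 2.64 ± 0.14), chaperones in 19 of 19 (median 0.76), cholesterol synthesis in 14 of 17 (median 2.05; Sqle 3.25 ± 0.10), tRNA synthetases in 16 of 18 (median 1.38; Yars 2.97 ± 0.11), nucleotide synthesis in 18 of 21 (median 1.06; Mthfd2 3.35 ± 0.19) and translation factors in 15 of 18, or 16 adjusted over the list alone (median 0.72). Proteasome genes (19 of 28, median 0.38, adjusted p = 0.00340), G1/S genes (17 of 32, adjusted p = 0.0400, and adjusted p = 0.159 with an estimated correlation; Ccnd2 5.09 ± 0.11) and Pol II genes (11 of 23, adjusted p = 0.0375, and adjusted p = 0.209 with an estimated correlation) leaned the same way. MHC class II genes responded more negatively in B cells in 9 of 11 (median -1.11, adjusted p = 0.00104, and adjusted p = 0.226 with an estimated correlation; H2-DMa -5.65 ± 0.11). Some marker lists leaned the same way, with differences towards T cells in 11 of 12 B cell markers (median -1.89) and 7 of 8 monocyte, macrophage and neutrophil markers (median -3.73). Red pulp macrophage genes did so in 11 of 11 (median -5.79), but their median level lay near the floor in T cells at 0 h and at 4 h. Their difference thus mostly restates the fall in B cells. Late erythroid genes also went towards T cells in 5 of 7 (1 the other way, median -1.37), as did plasma cell markers in 2 of 2 and stromal and endothelial markers in 2 of 2. Some members of these lists lay near the floor in T cells at 0 h and 4 h too, such as Cd79a (2.34 and 2.34), Csf1r (2.71 and 2.43) and Alas2 (2.24 and 2.24). Others did not, such as Cd79b (7.65 and 7.11). For those near the floor the difference likewise mostly restates the fall in B cells. Other marker lists leaned towards B cells, with 6 of 12 T cell markers (3 the other way, median 0.57), 3 of 4 dendritic cell markers (1 the other way, median 1.94) and 8 of 12 erythroid progenitor genes (median 1.09). The largest positive differences were Hspa1b (11.63 ± 0.18) and Hspa1a (10.99 ± 0.12), heat shock genes that stood at 12.52 and 8.48 in T cells at 0 h and at 4.44 and 2.24 in B cells at 0 h, and Jun (7.19 ± 0.33). The largest negative differences were Marchf1 (-9.37 ± 0.08), Frmd4b (-8.88 ± 0.20), Lrrk2 (-8.03 ± 0.20), Trim7 (-8.01 ± 0.17) and Srpk3 (-7.48 ± 0.19). Of these, Marchf1, Lrrk2, Trim7 and Srpk3 lay near the floor in T cells at 0 h and at 4 h. In all, 2830 genes differed towards B cells and 3152 towards T cells, a majority that turned with array medians set equal (3198 and 2880) and after cyclic loess (3053 and 3043).

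Across all 9045 genes the 4 h responses of B and T cells correlated with Pearson's r = 0.523 and Spearman's rho = 0.620, and genes are not independent replicates. Genes that rose in both numbered 2186, against 1137 expected from independence, and 2198 fell in both, against 1242 expected. A further 292 genes rose in B cells and fell in T cells, and 379 did the opposite. In T cells the 4 h and 14 h responses correlated with r = 0.830 and rho = 0.793, with 2346 genes that rose in both (1106 expected) and 2183 that fell in both (936 expected). Part of this excess may come from the shared 0 h arrays, which are too few to split: simulated data without any effect gave r = 0.500. Their simulated covariance was 0.00916, against 0.843 in the data, so noise in the shared arrays accounts for little of the covariance. A difference common to all 0 h arrays was not simulated.

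The number of genes at or above level 5 was lower after activation. It fell by 407 genes in B cells. In T cells it fell by 121.333 at 4 h, and at 14 h it fell by 93. Each exact permutation test, two-sided, gave p = 0.1, the smallest that 3 against 3 arrays can give. The T cell values depended on the level: at 4 h they were -99 at level 6 (exact p = 0.2) and -78 at level 7 (exact p = 0.3), and at 14 h -39 at level 6 (exact p = 0.4) and 14.3 at level 7 (exact p = 0.8). Between 14 h and 4 h it was 28.3 genes (exact p = 0.5), and between B and T cells at 0 h it was -230.0 (exact p = 0.1).

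Among changed genes, those of higher mean level had more often risen. The share that rose in B cells was 32.8% in the lowest of 5 bins of 1809 genes and 54.3% in the highest. In T cells it was 37.6% and 59.3% at 4 h, and 42.0% and 60.4% at 14 h. This trend depends on the normalization: after cyclic loess, which removes level-dependent differences between arrays by construction, the highest bin exceeded the lowest by 3.22 points at 4 h and 5.07 at 14 h in T cells, and in B cells the difference turned to -1.07 points.

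**Figure D3:**
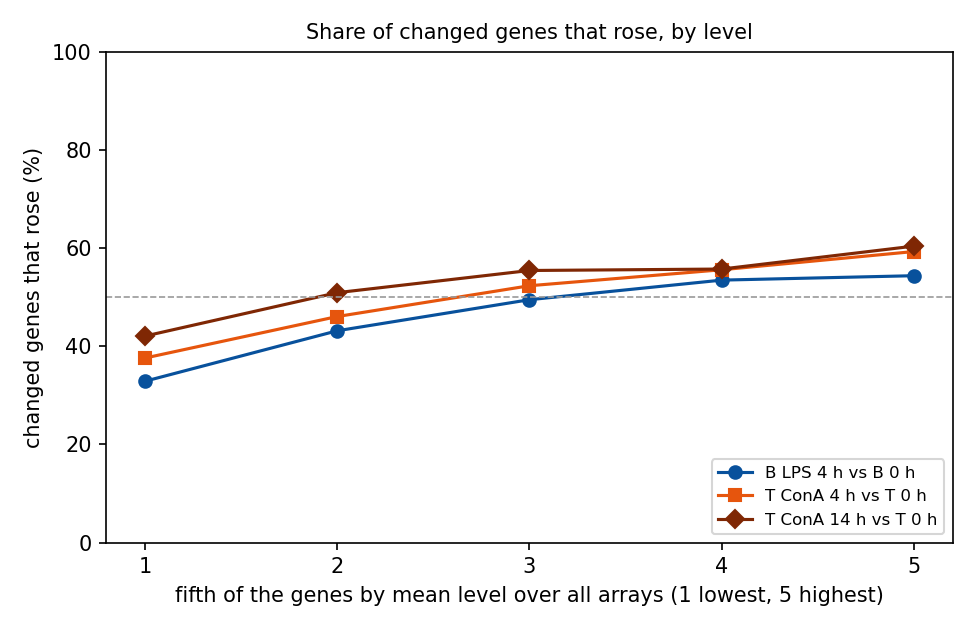
Percentage of changed genes that rose (y axis) in 5 equal bins of the mean log2 level over all arrays (x axis), for the 3 activation comparisons, with a dashed line at equal numbers of rises and falls. The share went from 32.8% to 54.3% for B cells, from 37.6% to 59.3% for T cells at 4 h and from 42.0% to 60.4% at 14 h.

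**Figure D4:**
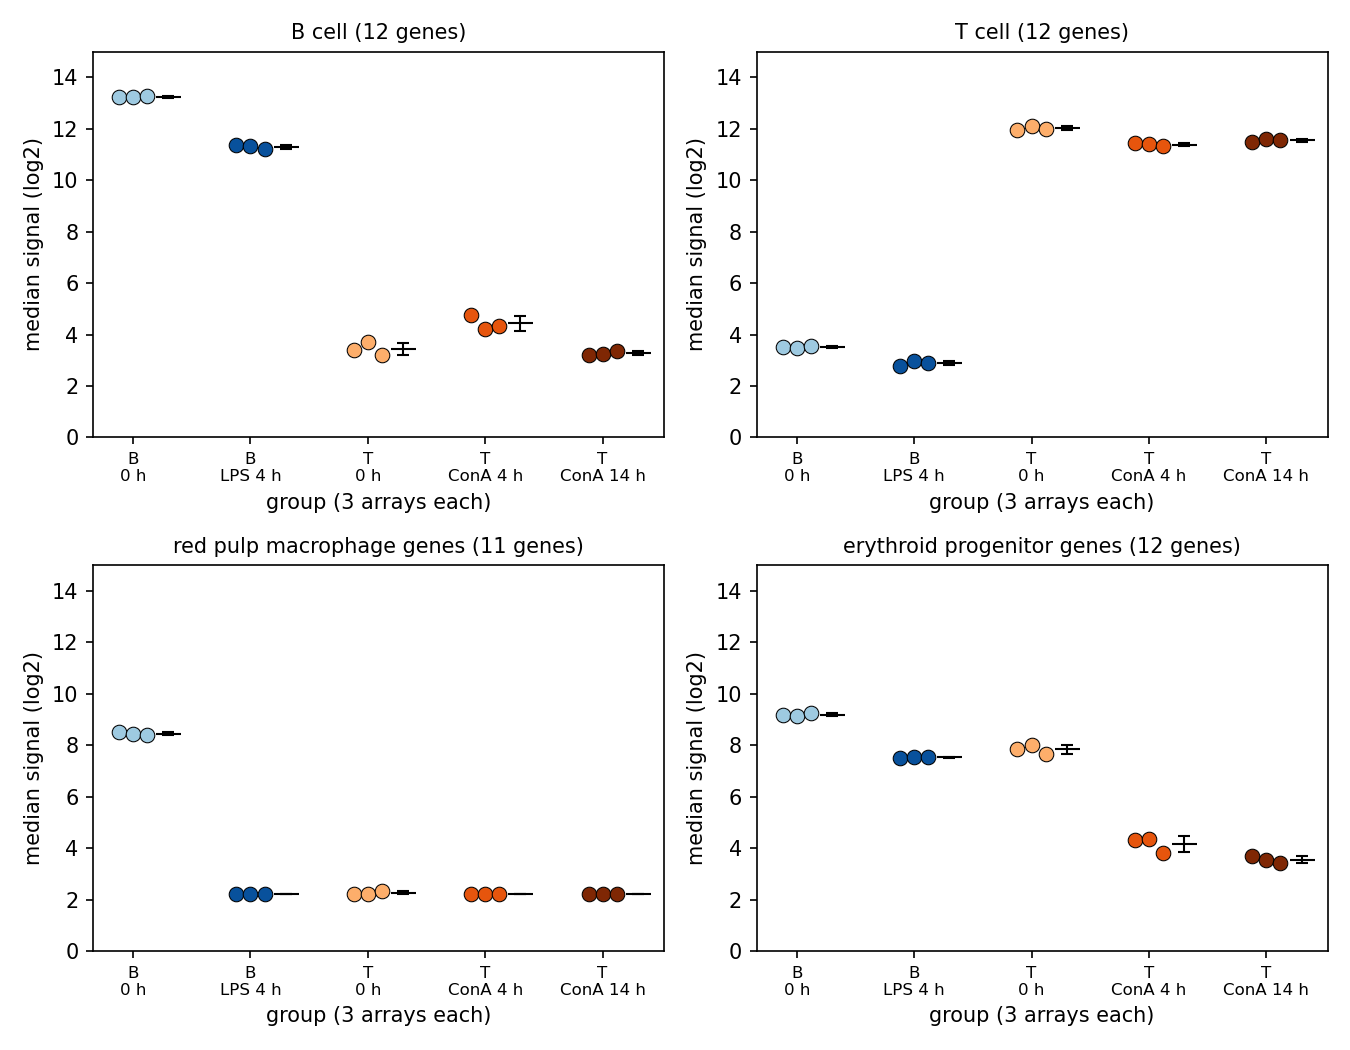
Median log2 signal per array of 4 marker lists, with the mean and SD of the 3 arrays beside each group. Red pulp macrophage genes fell by a median of -5.89 in B cells after LPS, and erythroid progenitor genes fell by a median of -2.39 at 4 h and -3.60 at 14 h in T cells.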

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

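The tests of the macrophage genes, of Xist and of the 2 T cell arrays were chosen only after the results were seen, as were the splits of the interaction with cell type and time differences removed, while the other counts over splits of the arrays followed a rule set beforehand.

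The 4 h responses to LPS in B cells and to ConA in T cells differed by the interaction test, which called 5982 genes. Cell type and stimulus cannot be told apart here, since B cells received only LPS and T cells only ConA. The 4 h response of Myc exceeded that in T cells by 2.96 in B cells. Hspa1b (11.63), Hspa1a (10.99), Ifit1 (9.55), Oasl1 (7.43) and Jun (7.19) differed most towards B cells, and Marchf1 (-9.37), Frmd4b (-8.88), Lrrk2 (-8.03), Trim7 (-8.01) and Srpk3 (-7.48) most towards T cells. The lists called had median differences of 3.79 for interferon-stimulated genes, 2.05 for cholesterol synthesis, 1.38 for tRNA synthetases, 1.06 for ribosome biogenesis and 1.06 for nucleotide synthesis. Those of chaperones (0.76), translation factors (0.72), the proteasome (0.38), Pol II genes (0.30), G1/S genes (0.26) and MHC class II genes (-1.11) completed the set. The last 3 lost their calls, with adjusted p = 0.209, 0.159 and 0.226 with an estimated correlation.

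Responses also differed between time points in T cells, where 4427 genes differed between 14 h and 4 h. The named genes were Xist (8.58), Lag3 (5.39), Tg (4.63), Ccl22 (4.44) and Selp (3.18), and in the other direction S100a9 (-6.005), S100a8 (-5.52), Mpzl2 (-4.14), St6galnac3 (-4.09) and Prag1 (-3.82). The lists called had medians of 0.90 for cholesterol synthesis, 0.74 for G1/S, 0.62 for glycolysis, 0.36 for oxidative phosphorylation and 0.33 for the proteasome. Immediate early genes (-0.63), cytokine feedback genes (-0.49) and G2/M genes (-0.28) had negative medians. Oxidative phosphorylation, cytokine feedback genes and G2/M genes lost their calls, with adjusted p = 0.110, 0.0782 and 0.210 with an estimated correlation.

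Data outside the comparisons gave signals too. Of 2895 probe sets without a single gene that reached level 5, 967 rose in B cells after LPS, and 790 and 500 rose in T cells at 4 h and 14 h. Probe sets for 18S ribosomal RNA exceeded every T cell array of 0 h: those of its 5' part averaged 12.40 at 4 h and 11.93 at 14 h, against 10.82 ± 0.41 at 0 h (SD, n = 3), and those of its middle part averaged 10.87 at 14 h.

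Splits of 3 against 3 arrays number 10, too few for a share under 0.05. With only the arrays compared in the fit, the real split called 7094 genes for LPS in B cells, 5735 and 6432 for ConA at 4 h and 14 h, 4230 for 14 h against 4 h, and 6862 for B against T cells, and in each case the highest other split called 0, so that 1 of the 10 splits gave as many. For gene lists the real splits called 18, 17, 19, 8 and 6 in the same order, against 19, 18, 16, 7 and 4 in the highest other split, and the number of splits with as many was 2, 3, 1, 1 and 1. Every other split keeps 2 arrays of a group together, as the one with 19 lists did with LPS replicates 2 and 3. Part of the real difference stays in such a split, so these list counts do not test chance. For the interaction 100 of the splits that regroup B and T labels within each time were used, and 2 gave as many genes as the real split (5788), the highest other being 7533. For the 11 lists 9 of the 100 gave as many, the highest other being 12. Mixed splits put the difference between B and T cells into the error, and the one with 7533 genes exchanges all B and T arrays at 4 h, so these counts do not test the interaction. With cell type and time differences removed first, only the real split, 1 of the same 100, gave as many as 5788 genes, and the highest other gave 0. Mixed splits then put the interaction itself into the error, which lowers their counts. The replicates may not be separate animals or cultures, so that result does not exclude chance differences between cultures. For the lists 7 of the 100 gave as many as the real 11, the highest other being 12. Mixed splits can likewise keep part of the interaction, so this count does not decide on chance, which was not excluded.

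Genes of red pulp macrophages fell together in the B cell arrays after LPS, for example C1qa from 9.50 to 2.24 and Vcam1 from 11.14 to 4.82, and Csf1r fell with them. The other 6454 genes with levels in the same range at 0 h had a median change of -0.0629, while the macrophage gene that fell least fell by 3.63. The macrophage genes thus fell further than most genes of their level. Normalization between arrays holds such a median near 0, so it cannot decide on poor labelling. An equal loss of every other cell type is argued against by the late erythroid genes, of which Bpgm fell most, at -2.18. Fewer macrophages in the 4 h cultures and macrophages still present that changed their genes under LPS cannot be told apart, since all 11 genes fell, as both require. The LPS-induced macrophage genes that were not tested reached at most 4.86 (Cxcl1, from 2.25 at 0 h). Untested genes lie under the level of 5 because of the filter itself, so they decide nothing. Of the LPS-induced genes, the 3 tested rose, Il12b by 4.17, Acod1 by 3.29 and Ptgs2 by 1.07. Acod1 and Ptgs2 also rose in T cells. The T cell arrays held monocyte and neutrophil signal too, with S100a8 going from 7.48 at 0 h to 10.19 at 4 h and Lyz2 from 7.16 to 6.18. Whether lymphocytes or other cells expressed the LPS-induced genes was not tested, in either preparation.

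Xist read near the floor at 4 h in both cell types and returned to 11.77 in T cells at 14 h, and a lasting loss with activation is argued against by its change of -0.48 between 0 h and 14 h (a short-lived loss in the same cells was not tested). A different mix of male and female animals is a candidate explanation in T cells, where the median of the Y-linked genes rose by 0.53 at 4 h and changed by -1.57 from 4 h to 14 h. Single X-linked homologues changed by like amounts at 4 h, Eif2s3x by 0.58 and Kdm6a by -0.68, but in opposite directions. At 14 h against 0 h the Y-linked genes (median -0.79) and Xist (-0.48) both fell in T cells, while a change of mix alone would move them in opposite directions. In B cells the median change of the Y-linked genes was -0.00532, and a mix with few female animals at 0 h cannot be told apart from a loss of Xist without one, since the share of female cells is not known. A dimmer probe set of Eif2s3y weakens the B cell value, as it fell from 5.21 to 2.45 in B cells but read 2.24 in T cells at 0 h, where the brighter one read 10.73, and why they disagree was not tested.

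Myc was lower on T 0 h replicate 2 and T ConA 4 h replicate 1 than on the other arrays of their groups. Short labelled RNA on these 2 arrays is a candidate explanation: their deviations from the group means correlated at 0.575 across genes, against at most 0.353 for the other of the 90 pairs of arrays from different groups, and both had the weak 5' spike-in signal. That the rise of Myc at 4 h came only from these arrays is argued against by its value of 2.12 without them (adjusted p = 3.01e-06; over all its alternatives the rise kept its direction). No biological explanation was tested.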

How the results depend on the processing

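The alternatives without the 2 T cell arrays, with the spike-in covariate and without genes under 4 were chosen after the data were seen; the others were planned. Of the 81 list results that were called, under 630 settings, 583 kept their direction and their side of the threshold, 47 kept only the direction and 0 reversed. Among lists not called the median changed sign under another normalization for 10 lists in B against T cells at 0 h. It did so for 2 at 4 h, for 2 at 14 h against 4 h and for 1 in the interaction. In B against T cells the 10 flipped when array medians were set equal, which moves every gene alike by 0.25. A list with a small negative median flips under such a move whatever its genes do. Of 348 settings of marker list medians, 286 moved by less than the spread between arrays, 62 moved by more and 0 reversed. A reversal was counted only for lists with most members called in the direction of the median. Changes of sign in the other marker lists were not counted. Of 5678 settings of 293 results for named genes, 5598 kept direction and side, 49 were weaker, 17 stronger and 14 reversed.

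Leaving out 1 array at a time gave 7018 to 7088 changed genes for LPS in B cells, 5614 to 5917 for ConA at 4 h, 5804 to 5878 at 14 h, 3819 to 4337 for 14 h against 4 h, 6610 to 6723 for B against T cells and 5754 to 6067 for the interaction. A replicate block gave 7162, 5889, 6099, 4286, 6860 and 5867 in that order. Of 30 pairs of arrays with the same replicate number, 3 had deviations correlated above 0.1. The highest such correlation was 0.236, against 0.575 among pairs with different numbers. These values gave no sign of pairing by number but cannot exclude it.

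In the same order, testing every probe set on its own gave 14495, 11689, 12497, 9000, 14434 and 11834, from more features tested. Requiring at least a 2-fold change gave 3870, 1889, 1946, 676, 2944 and 2931, and treat against 1.5-fold gave 4443, 2193, 2364, 692, 3408 and 2948, both stricter by construction.

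Lists called with an estimated correlation numbered 5 for 14 h against 4 h and 1 for B against T cells, and fry called 20 and 22 there and 22 for the interaction, as it compares a list with no other genes. Genes above the level at 14 h against 0 h differed by 14.3 at level 7, and at 14 h against 4 h by -265 over every probe set; the cause was not tested.

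The share of changed genes that rose, highest minus lowest bin, was 21.5 points for LPS in B cells. It was -1.07 after cyclic loess, 16.8 with a filter at 7 and 15.5 without genes under 4. For ConA at 4 h it was 21.7, then 3.22 after cyclic loess and 16.9 without genes under 4. At 14 h it was 18.3, then 5.07 and 11.4. No level filter gave no value, since its lowest bin held no changed genes. Cyclic loess removes such trends by construction; the cause of the other shifts was not tested.

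The correlation of the 4 h responses was 0.523, and 0.508 with no filter, 0.549 with a filter at 7 and 0.609 without genes under 4. That of 4 h and 14 h in T cells was 0.830, and 0.814 without genes under 4. The cause was not tested. Reversed gene values lay mostly in genes that had not passed. Myc at 14 h against 4 h was 0.30, but -0.29 with the spike-in covariate and -0.31 without the 2 T arrays or without T ConA 4 h replicate 1 alone, and at most 0.61 (without replicate 2). After LPS, Kdm5d was -0.00532, against 0.0878 over the mean of its probe sets, 0.0664 with medians set equal, 0.00138 with quantile normalization, 0.00320 with the covariate, and -0.147 to 0.138 leaving out 1 array. Uty turned to 0.0963 over the mean of its probe sets and 0.0231 after cyclic loess, and Pf4 to 0.0464 after cyclic loess. Eif2s3y after LPS turned from 0.17 to -1.29 over the mean of its probe sets (adjusted p = 9.55e-07), since its dimmer probe set fell. Slc2a3 at 14 h was 0 without the probe sets that may match other transcripts, since its remaining probe set lay at the floor.

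Signal near the floor, with 63.6% of all values under 5, limits what weakly expressed genes can show.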

Other observations

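The erythroid progenitor, late erythroid and X-linked homologue lists and the globin probe sets were chosen only after the results were seen. Car1, Ermap, Alas2, Epb42, S100a8 and S100a9 also stand in marker lists fixed beforehand, and Hspa1b was named by the fixed rule.

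Genes of red blood cell precursors were present in both resting preparations. In T cells at 0 h members of the erythroid progenitor list ranged from the carbonic anhydrase Car1 (12.18), Car2 (9.91), Ermap (8.13) and Klf1 (7.94) down to Rhag (5.23), Epor (4.69) and Icam4 (3.45). Those of the late erythroid list ranged from Slc25a37 (8.90), Bpgm (8.06) and Hemgn (6.26) down to Slc4a1 (3.71), Trim10 (2.30) and, at the floor of 2.24, Alas2 and Epb42. In B cells at 0 h Slc4a1 read 12.69, Alas2 10.16, Car1 9.17 and Klf1 9.18. All 12 erythroid progenitor genes (median -1.45) and 7 of 7 late erythroid genes (median -1.46) fell in B cells after LPS. In T cells late erythroid genes fell in 4 of 7 at 4 h (Hemgn -1.89 ± 0.11) and in 3 of 7 at 14 h. Globin RNA was seen on probe sets shared by several globin genes, which the gene-level tests left out. The one for Hbb genes read 14.62 in B cells at 0 h, 14.31 after LPS, and 8.27, 7.45 and 5.64 in T cells at 0 h, 4 h and 14 h.

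The heat shock gene Hspa1b read 12.52 in T cells at 0 h, 7.42 at 4 h and 5.93 at 14 h, and in B cells it read 4.44 at 0 h and 10.97 after LPS. The neutrophil genes S100a8 and S100a9 read 7.48 and 6.20 in T cells at 0 h, 10.19 and 8.65 at 4 h, and 4.67 and 2.65 at 14 h. The X-linked homologues of the Y-linked genes went both ways in B cells after LPS, with Eif2s3x rising (0.61 ± 0.12) and Kdm6a falling (-1.31 ± 0.11).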
